A study of Bos taurus with 10 samples.

How the data were processed

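The labels describe muscle RNA from cattle of 24 months in which 1 copy of MSTN, the gene of the muscle growth inhibitor myostatin, was edited (7 libraries), and from wild-type cattle of the same age (3 libraries). RNA was taken from frozen tissue with Trizol and made into Illumina libraries, per the labels' protocols. Nothing in the labels says how many animals the libraries came from, so p-values measure the spread between these libraries, which may be partly technical. Groups were taken from the genotype label, the replicate numbers only name libraries, in the order of the sample records and not from the labels, and each column of the table was tied to its library by the library title in the column name. No column of per-library values was left unused.

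The table holds 1 FPKM value (fragments scaled by transcript length and by the mapped fragments of the library) per gene and library, made by the authors, per the file headers, and rounded to 2 decimals. The aligner, counting tool, genome build and filters are not given in the sources used here. The 21130 rows carry a gene identifier, transcript accessions, a symbol and a description. The organism in the descriptions did not match the label: 19415 rows named Mus musculus. Against a RefSeq gene table of cattle, 0 gene identifiers and 0 of 30319 transcript accessions matched. The symbols of 15058 rows were also cattle symbols or synonyms without regard to case, a match of names that cannot tell the species. In 900 rows the symbol was blank, and 27 symbols had been turned into calendar dates. Because the mismatch leaves the origin of the values open, groups are called "labelled MSTN+/-" and "labelled wild type", and no difference is attributed to the genotype or to cattle muscle.

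FPKM values are not counts, so no count test was run, and total depth per library is unknown. Relative depth was estimated from 896 low genes with a single transcript that were listed at 0 in at least 4 libraries, in which values lie on steps of single fragments. The modal step ratio put the libraries at 1 to 1.20 times the depth of MSTN+/- replicate 1. It was searched only near equal depth, so a large difference between libraries could not have been returned.

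Differences were fitted with limma 3.58.1 (R 4.3.3) on log2(FPKM + 1), with an intensity-dependent prior, for the 14047 genes at 1 FPKM or more in at least 3 libraries, with no covariate and 8 residual degrees of freedom. A fold change is therefore on the log2(FPKM + 1) scale, which understates changes of low genes. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Gene lists were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01 between genes, for lists with at least 4 members tested. The Mstn level and the share of slow myosin were compared with exact two-sided permutation tests over all 120 ways of choosing 3 of the 10 libraries, whose smallest possible p is 0.00833.

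The main tests, the alternatives, 33 gene lists suited to cattle muscle and the rule for named genes were set before the data were examined. That rule takes Mstn, then, of genes past the threshold with a symbol and a mean of at least 5 FPKM in 1 group, the 10 with the largest positive and the 10 with the largest negative log2 change, and from each list described in detail 2 or 3 members with the smallest p. List symbols were matched without regard to case or through mouse equivalents, and 558 of 580 were found. The 13 mitochondrially encoded genes had no row. Lists of skeletal muscle transcripts, pluripotency markers, fibroblast markers and rodent-only transcripts were added after the data were seen. So were a list of genes of major histocompatibility complex (MHC) class I presentation and the fit against wild-type replicate 1 alone.

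Alternatives were median-of-ratios, TPM and quantile normalization, a pseudocount of 0.1, no low-value filter, a mean of at least 5 FPKM, robust empirical Bayes, library weights, an estimated correlation in camera, and leaving out each library in turn. The procedure was tested on simulated data for the same comparison and 14047 genes, drawn with each gene's own residual spread. Among genes with a mean log2(FPKM + 1) of at least 3, it recovered 52% of 50 genes changed 2-fold, 80% of 50 changed 4-fold, 94% of 50 changed 8-fold and 100% of 50 changed 16-fold, and 4.68% of its 171 calls were false. The simulated values were independent between genes and had the same spread in both groups. These rates therefore do not cover wild-type libraries that differ from one another, or genes that move together. Figures were drawn with matplotlib 3.10.9.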

Results

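The deposited table held FPKM values for 10 libraries, 7 labelled as muscle of cattle heterozygous for an edited MSTN gene (MSTN+/-) and 3 labelled as muscle of wild-type cattle. The series was designed to compare the muscle mRNA of the 2 genotypes. FPKM totals ran from 402716 in wild-type replicate 1 to 464418 in MSTN+/- replicate 3, and 11856 to 13858 genes reached 1 FPKM. Estimated relative depth ran from 1 in MSTN+/- replicate 1, the reference, to 1.20 in wild-type replicate 1, from a search limited to small ratios. The table gives no coordinates, so genes are identified by symbol and by the gene identifier in the table.

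The contents did not match the labelled species and tissue. Of 21130 rows, 19415 were described as genes of Mus musculus. Most transcripts that dominate skeletal muscle were near 0. Of 30 such transcripts, a list drawn up after the values were seen, 10 stayed below 1 FPKM in all 10 libraries and 5 reached 10 FPKM in at least 1. The muscle creatine kinase gene Ckm was at 0.13 to 1.07 FPKM, the titin gene Ttn at 0.01 to 0.40 FPKM, and the skeletal actin gene Acta1 at 2.66 to 24.43 FPKM. The exception was Mylpf, a fast myosin light chain gene, at 155 and 125 FPKM in wild-type replicates 2 and 3, 0.75 FPKM in replicate 1 and 6.24 to 26.7 FPKM in the MSTN+/- libraries. The enolase gene Eno3 was at 9.41 to 25.99 FPKM, and Myh2 and Des reached at most 15.3 and 11.97 FPKM. The median of the 30 muscle transcripts was 0.12 to 0.56 FPKM across libraries, while the median of all genes tested was 7.73 to 10.48 FPKM. The differences below are therefore differences between columns carrying these labels, and none can be read as an effect of MSTN in cattle muscle.

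**Figure D1:**
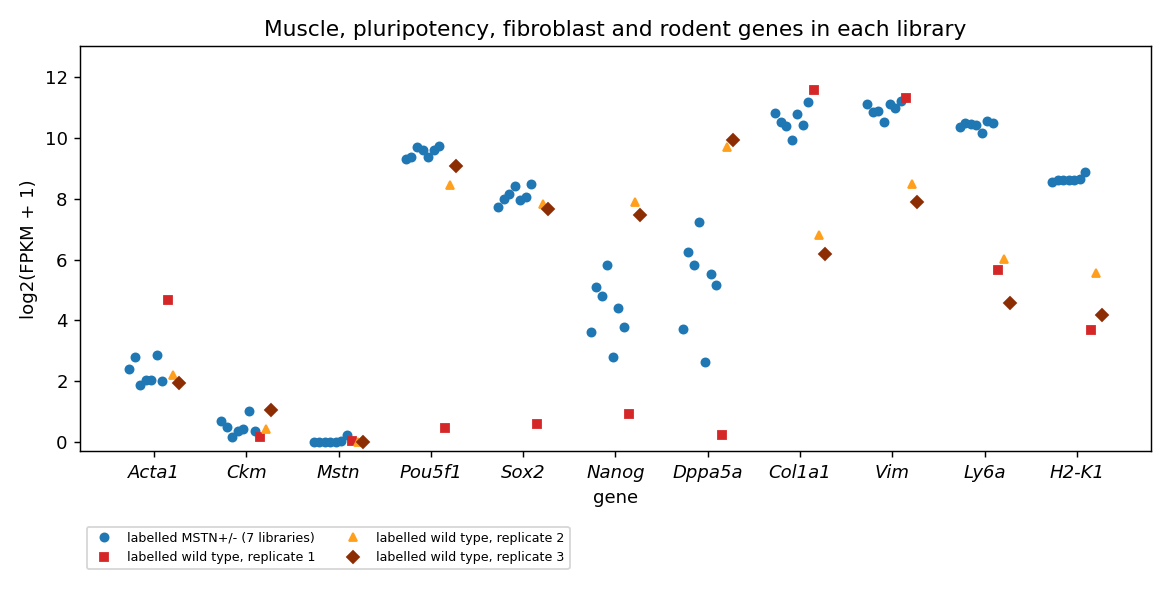
Values of 11 genes in each of the 10 libraries, as log2(FPKM + 1), 1 point per library; blue circles are the 7 libraries labelled MSTN+/-, and the square, triangle and diamond are wild-type replicates 1, 2 and 3. Ckm and Mstn lie near 0 in every library, while Pou5f1 is at 633 FPKM or more in all 7 MSTN+/- libraries, 0.38 FPKM in wild-type replicate 1 and 346 and 533 FPKM in wild-type replicates 2 and 3.

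Genes of other cell types were abundant, and the 3 wild-type libraries differed in them. Pou5f1 and Sox2, transcription factors of pluripotent cells, were at 633 to 848 and 212 to 357 FPKM in the 7 MSTN+/- libraries. In wild-type replicates 1, 2 and 3, Pou5f1 was at 0.38, 346 and 533 FPKM. Nanog, another pluripotency factor, was at 5.95 to 55.0 FPKM in the MSTN+/- libraries and at 0.91, 234 and 177 FPKM in the wild-type libraries. Col1a1, the collagen I chain made by fibroblasts, was at 969 to 2329 FPKM in the MSTN+/- libraries, at 3017 FPKM in wild-type replicate 1, and at 110 and 72.2 FPKM in wild-type replicates 2 and 3. The median of 27 pluripotency markers was 2.18 to 18.2 FPKM in the MSTN+/- libraries and 0.06, 96.6 and 120 FPKM in the wild-type libraries. The median of 18 fibroblast markers was 89.9 to 148 FPKM in the MSTN+/- libraries and 132, 17.3 and 7.67 FPKM in the wild-type libraries. Both marker lists were drawn up after the values were seen.

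Across genes, which are not independent replicates, the 7 MSTN+/- libraries correlated with one another at Pearson's r of 0.954 to 0.985. Wild-type replicates 2 and 3 correlated at 0.975, but wild-type replicate 1 correlated with them at 0.773 and 0.751, below its 0.847 to 0.876 with the MSTN+/- libraries. The first principal component held 63.2% of the variance and the second 22.7%. On the first, wild-type replicates 2 and 3 were at 110 and 123, wild-type replicate 1 at 5.86 and the MSTN+/- libraries at -48.3 to -17.6. The second set wild-type replicate 1 apart, at -106, from all other libraries, at -1.14 to 27.2. Neither component separated the labelled groups alone.

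**Figure D2:**
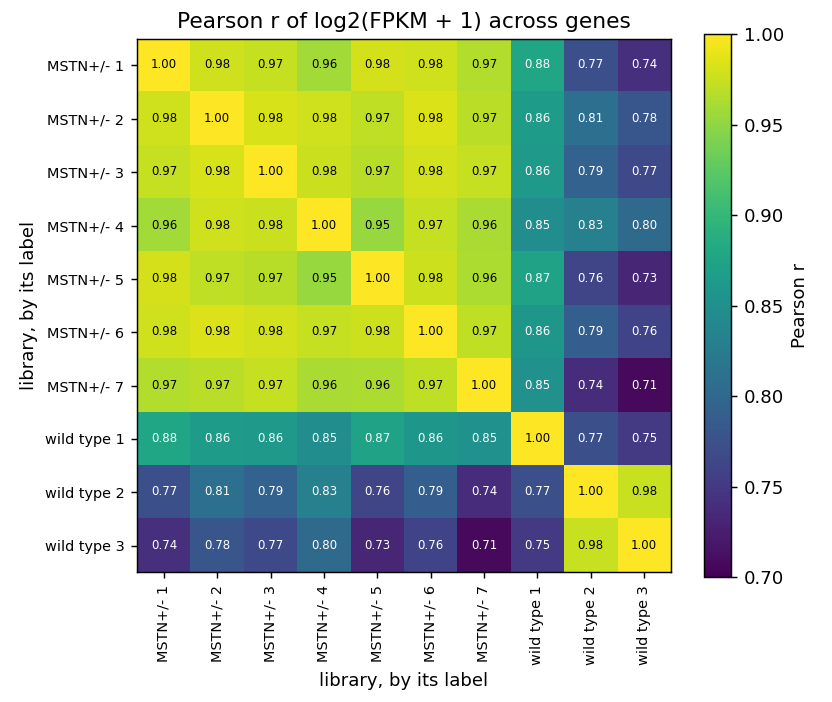
Pearson's r of log2(FPKM + 1) across the 14047 genes tested, for every pair of the 10 libraries, coloured from 0.7 to 1. Wild-type replicates 2 and 3 form a pair at 0.98, and wild-type replicate 1 lies closer to the 7 MSTN+/- libraries (0.85 to 0.88) than to that pair (0.77 and 0.75).

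The first question for an edited gene is its own transcript. Mstn (gene 17700) was listed at 0 FPKM in 7 of the 10 libraries, at 0.04 and 0.18 FPKM in MSTN+/- replicates 6 and 7, and at 0.03 FPKM in wild-type replicate 1. The groups' mean log2 values differed by 0.03, and the exact permutation test gave p = 0.767 over 120 splits (two-sided). At this level Mstn cannot check the genotype labels.

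The comparison of the labelled groups separated a large part of the genes. In limma, 4468 genes were higher and 1800 lower in the libraries labelled MSTN+/- at an adjusted p under 0.05, and 2730 of these differed by at least 1 on the log2 scale. All 7 MSTN+/- values lay above all 3 wild-type values for 3538 genes and below them for 963, together 32.0% of genes tested, where chance would give 1.67%. The split by direction depended on scaling. The higher share of the calls was 71.3% as deposited, 65.0% after TPM rescaling, 51.7% after median-of-ratios scaling and 42.7% after quantile normalization. The median log2 change of all genes was 0.17 as deposited and 0.15, 0.01 and -0.10 under those scalings, so changes are best read relative to that shift. The count of lower genes was 4449 without wild-type replicate 1, 793 without replicate 2 and 791 without replicate 3. Against wild-type replicate 1 alone, a fit chosen after seeing the data that assumes this library varies like the 7, 4633 genes were higher and 1478 lower, and these shared 2765 and 398 genes with the calls from all libraries.

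The 10 largest increases were genes of several classes, at 10.1 FPKM or less in all 3 wild-type libraries. Crym (gene 12971), which encodes a thyroid hormone-binding protein, had 634 ± 85.6 FPKM (SD, n = 7) in MSTN+/- libraries and 0.983 ± 0.605 FPKM (SD, n = 3) in wild type, a log2 change of 8.36 with a standard error of 0.19 (limma adjusted p = 3.204e-09). Aldh3a1 (gene 11670), an aldehyde dehydrogenase, had 269 ± 65.8 FPKM against 0.21 ± 0.18 FPKM, a log2 change of 7.78 ± 0.21 (SE, limma adjusted p = 7.949e-09). Ifi27l2a (gene 76933), an interferon-induced gene, had 407 ± 88.9 FPKM against 1.75 ± 2.48 FPKM, and the secreted proteoglycan gene Prelp had 377 ± 52.8 FPKM against 1.21 ± 0.94 FPKM. Ly6c1, a surface protein gene of the mouse Ly6 cluster, had 508 ± 69.7 FPKM against 6.74 ± 3.55 FPKM, and shares sequence with near copies such as Ly6c2, so its reads may have been split. The other 5 were Fndc1, Lbp, which encodes a lipopolysaccharide-binding protein, the kallikrein gene Klk1, the apolipoprotein gene Apod and the proteoglycan core gene Srgn, with log2 changes of 6.05 to 6.54. Values of all 10 lay above every wild-type library in 7 of 7 MSTN+/- libraries.

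The 10 largest decreases were less uniform, and 5 of them overlapped between groups. Spp1 (gene 20750), which encodes osteopontin, had 86.5 ± 35.4 FPKM in MSTN+/- libraries and 646 ± 83.9 FPKM in wild type, a log2 change of -2.98 with a standard error of 0.33 (limma adjusted p = 8.197e-05). The kinase gene Sgk1 had 13.4 ± 4.96 FPKM against 138 ± 76.1 FPKM, a log2 change of -3.15 (limma adjusted p = 2.622e-04). Il1rl1, the interleukin 33 receptor gene, was at 2.71 to 4.74 FPKM in MSTN+/- libraries and at 271, 60.1 and 16.1 FPKM in wild-type replicates 1, 2 and 3, a log2 change of -3.85 that was -2.21 with library weights and -5.90 against wild-type replicate 1 alone. Fosb, a subunit of the AP-1 transcription factor, and the protease gene Mcpt8 had log2 changes of -3.11 and -2.55. Klf2, Klf5, Nlrp4f, Rbpms2 and Fabp3 overlapped between groups. In wild-type replicate 1 they were at 23.5, 9.19, 0.03, 22.4 and 17.6 FPKM, within the MSTN+/- range, and in wild-type replicates 2 and 3 they were higher, as with Klf2 at 205 and 216 FPKM. Klf2, Klf5, Rbpms2 and Fabp3 missed the threshold without wild-type replicate 2 (limma adjusted p of 0.0585, 0.0825, 0.0573 and 0.219), without replicate 3 (0.0591, 0.0855, 0.0591 and 0.155) and against replicate 1 alone (0.437, 0.694, 0.440 and 0.945), where Fosb missed it too (0.105). Fabp3 also missed it without any 1 of MSTN+/- replicates 1, 2, 3, 5, 6 and 7 (0.0620 to 0.0765) and with no low-value filter (0.0623). Nlrp4f missed it with a pseudocount of 0.1 (0.0999) and without any 1 of MSTN+/- replicates 1, 5 and 6 (0.0501 to 0.0530). It fell below the low-value filter, and was not tested, without wild-type replicate 2, without replicate 3, against replicate 1 alone and without MSTN+/- replicate 4. Without wild-type replicate 1 its log2 change was -4.22 in place of -2.66, and without replicate 2 that of Fabp3 was -1.57 in place of -2.43. Mcpt8 was likewise not tested without any 1 wild-type library, against replicate 1 alone or at a mean of at least 5 FPKM. Against replicate 1 alone, Sgk1 had a log2 change of -2.01, past the threshold.

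**Figure D3:**
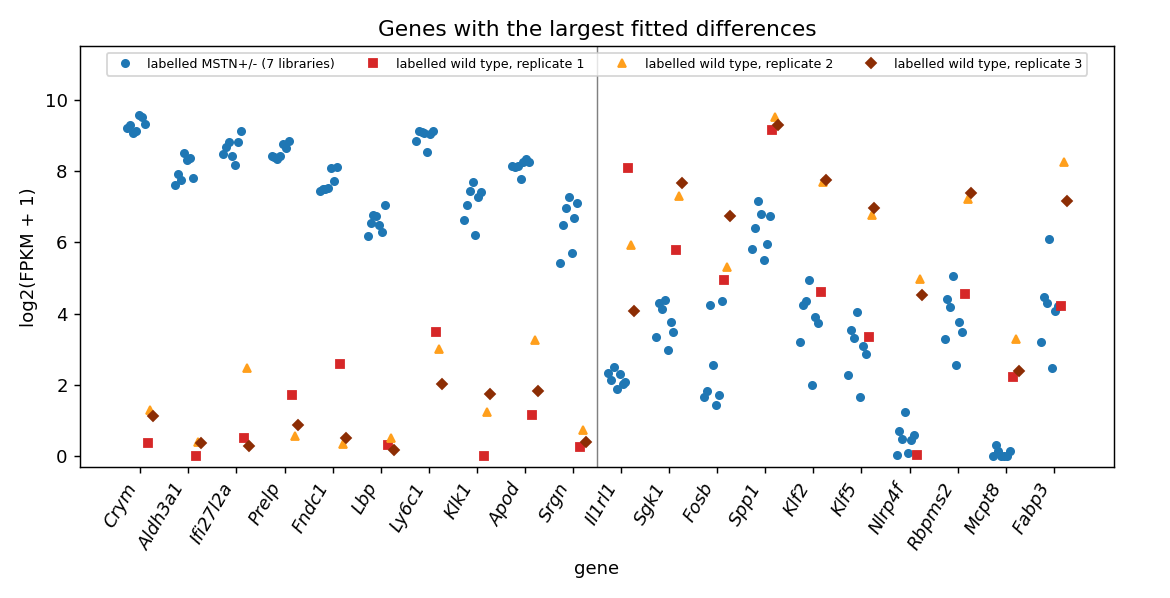
The 10 genes with the largest positive (left of the line) and the 10 with the largest negative (right) log2 change among genes past the threshold, as log2(FPKM + 1), with 1 point per library. The left genes are above all 3 wild-type libraries in all 7 MSTN+/- libraries, while on the right wild-type replicate 1 lies within or next to the MSTN+/- points for Klf2, Klf5, Nlrp4f, Rbpms2 and Fabp3.

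Of the 33 lists, 27 could be tested, and camera called 4 higher and 1 lower. None of the 5 calls held with an estimated correlation (adjusted p = 0.686 for each). Lists called lower numbered 3 without MSTN+/- replicate 1 or wild-type replicate 3, and 2 without MSTN+/- replicate 5 or wild-type replicate 1 or 2. Lists called higher numbered 7 without wild-type replicate 3. Interferon response genes were the most uniform: 15 of 15 members tested rose, also 15 when adjusted over the list alone, with a median log2 change of 3.02 (camera adjusted p = 1.227e-05), and 4.97 against wild-type replicate 1 alone. The antiviral GTPase genes Mx1 and Mx2 had 9.06 ± 1.83 and 7.34 ± 1.04 FPKM (SD, n = 7) against 0.23 ± 0.22 and 0.53 ± 0.63 FPKM (SD, n = 3), and the RNA sensor gene Ifih1 had 14.8 ± 2.66 FPKM against 1.49 ± 1.35 FPKM.

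Of 8 markers of fibro-adipogenic progenitors, the matrix-producing cells of muscle, 7 rose, also 7 when adjusted over the list alone (median log2 change 3.36, camera adjusted p = 1.534e-04). Clec3b had 78.2 ± 18.3 FPKM against 0.20 ± 0.18 FPKM, Pi16 had 19.9 ± 4.78 FPKM against 0.087 ± 0.090 FPKM, and Scara5 had 21.9 ± 4.98 FPKM against 0.50 ± 0.19 FPKM. Of 25 extracellular matrix genes, 15 rose and none fell, 18 when adjusted over the list alone (median 2.14, camera adjusted p = 0.00104). Examples were the proteoglycan gene Dcn, at 252 ± 48.8 FPKM against 21.9 ± 12.6 FPKM, and the collagen genes Col15a1, at 42.97 ± 13.02 FPKM against 0.58 ± 0.53 FPKM, and Col14a1, at 13.8 ± 2.47 FPKM against 0.88 ± 1.28 FPKM. Of the 18 fibroblast markers, 8 were higher and 10 did not pass the threshold. That list shares genes with these lists, such as Col1a1, Dcn and Pdgfra, so it gives them no separate support. Against wild-type replicate 1 alone, which had the highest Col1a1, the median of the matrix list was 0.10 and camera's direction turned to lower. Without wild-type replicate 1 its median was 3.46 and with library weights 3.40 (adjusted p = 7.834e-08 and 1.217e-08).

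In the circadian clock list 9 of 14 members rose and 1 fell, with the same counts when adjusted over the list alone (median 0.99, camera adjusted p = 0.0292). The clock output genes Dbp and Tef had 32.8 ± 8.60 and 24.9 ± 3.05 FPKM against 1.84 ± 0.78 and 8.77 ± 1.38 FPKM, and the clock repressor gene Nr1d1 had 29.9 ± 3.39 FPKM against 6.85 ± 2.85 FPKM. This call was lost without wild-type replicate 1 (adjusted p = 0.122), where the median was 1.06, and against replicate 1 alone (0.0792) and with library weights (0.182), in a range of 0.0134 to 0.686 over all alternatives. Its median was 0.50 with quantile normalization. Proteasome subunits were lower: 11 of 29 fell and none rose, 9 when adjusted over the list alone (median -0.38, camera adjusted p = 7.367e-06). Psmd11 had 53.5 ± 5.08 FPKM against 91.9 ± 24.0 FPKM, Psmd1 had 58.8 ± 7.01 FPKM against 90.1 ± 16.6 FPKM, and Psmc3 had 83.0 ± 9.69 FPKM against 122 ± 17.7 FPKM. The median of the pluripotency markers, though not Pou5f1, Sox2 or Klf4, was highest in wild-type replicates 2 and 3. These 3 subunits were also highest there. Against wild-type replicate 1 alone the proteasome median was 0.05. In that fit Psmd11, Psmd1 and Psmc3 missed the threshold, with log2 changes of -0.27, -0.28 and -0.31 (limma adjusted p of 0.170, 0.235 and 0.190) in place of -0.74, -0.60 and -0.55. The proteasome median was -0.25 without wild-type replicate 2 and -0.58 with median-of-ratios scaling.

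The lists closest to the question of muscle growth and fibre type were not called. TGF-beta, activin and BMP signalling, the pathway of myostatin, had 8 members higher, 3 lower and 19 not past the threshold (camera adjusted p = 0.923). Its member Id1, a BMP target, had 52.2 ± 9.80 FPKM against 14.3 ± 9.57 FPKM, and the inhibitor gene Smad7 had 5.32 ± 0.75 FPKM against 19.3 ± 8.65 FPKM. Against wild-type replicate 1 alone their log2 changes were 0.99 and -0.71 in place of 1.94 and -1.58, past the threshold. Myogenic regulators had 3 of 6 members higher and 1 lower (camera adjusted p = 0.510), among them the transcription factor genes Mef2d, at 32.8 ± 3.12 FPKM against 15.7 ± 2.69 FPKM, and Mef2a, at 25.0 ± 2.97 FPKM against 10.6 ± 4.76 FPKM, whose log2 change of 1.23 was 0.60 against wild-type replicate 1 alone. Slow fibre genes had 1 of 5 members higher, Myoz2 at 0.90 ± 0.39 FPKM and listed at 0 in all 3 wild-type libraries, and 1 lower, the tropomyosin gene Tpm3, also active outside muscle, at 185 ± 12.6 FPKM against 241 ± 26.3 FPKM (camera adjusted p = 0.665). The call of Tpm3 was lost with library weights, where its log2 change was -0.19 in place of -0.37 (limma adjusted p = 0.186), and without wild-type replicate 2 (0.0566), in a range of 0.00255 to 0.186 over its alternatives. That of Myoz2 was lost with quantile normalization (0.0588), with library weights (0.0686) and against wild-type replicate 1 alone (0.0562), in a range from 4.964e-04, and it was not tested at a mean of at least 5 FPKM or without any 1 of MSTN+/- replicates 2, 4 and 5. Fast fibre genes had 3 of 7 members higher (camera adjusted p = 0.483), with the myosin heavy chain genes Myh2 at 11.6 ± 3.41 FPKM against 0.053 ± 0.076 FPKM and Myh1 at 3.77 ± 1.58 FPKM against 0.32 ± 0.38 FPKM. These paralogs share sequence, so reads may be split between them. Adjusted over the list alone, the TGF-beta list had 6 members higher and 3 lower, and the myogenic, slow and fast lists kept the counts given.

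Metabolic lists came closest to the threshold without passing it. The TCA cycle had 1 member higher and 3 lower of 18 (camera adjusted p = 0.0554), the nuclear-encoded respiratory chain 5 higher and 7 lower of 43 (0.0669), and fatty acid oxidation 10 higher and 1 lower of 19 (0.0899). Atrophy ligases and autophagy had 9 members higher and 1 lower of 14 (0.0956), and insulin, IGF and mTOR signalling 7 higher and 5 lower of 23 (0.867). Cytosolic ribosomal proteins had 6 of 49 higher (0.273). Adjusted over the list alone, 1 ribosomal protein gene was higher, the TCA cycle had 1 higher and 2 lower, insulin, IGF and mTOR signalling had 8 higher and 5 lower, and the other 3 lists had the counts given. In 6 lists, the mitochondrially encoded chain and the adipocyte, erythrocyte, macrophage, lymphocyte and neutrophil markers, fewer than 4 members were tested, with 0, 3, 0, 3, 1 and 1. The signs of median, mean and test differed in 7 lists not called. Camera's direction was lower beside a positive median and mean for TGF-beta signalling (0.25 and 0.36), glycolysis (0.05 and 0.10), insulin, IGF and mTOR signalling (0.05 and 0.53) and branched-chain amino acid catabolism (0.27 and 0.12). It was also lower for fatty acid synthesis (0.11 and -0.02), slow fibre genes (-0.23 and 0.16) and heat shock genes (-0.45 and 0.04).

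Markers of other cell types of muscle and the stress lists were also not called. Endothelial markers had 3 members higher and 1 lower of 8 (camera adjusted p = 0.923), smooth muscle and pericyte markers 0 higher and 2 lower of 8 (0.149), Schwann cell and nerve markers 3 higher of 5 (0.163) and MHC class II genes 1 higher of 4 (0.665). Heat shock genes had 2 higher and 6 lower of 17 (0.163), and immediate early genes 4 higher and 4 lower of 19 (0.163). Glycolysis and glycogen genes had 4 higher of 18 (0.862), fatty acid and triglyceride synthesis 3 higher and 5 lower of 16 (0.267), and branched-chain amino acid catabolism 5 higher and 2 lower of 15 (0.990). Mitochondrial biogenesis and AMPK had 3 higher and 3 lower of 15 (0.163), excitation-contraction coupling 6 higher of 13 (0.510), and developmental and denervation genes 1 higher and 1 lower of 4 (0.862). Adjusted over the list alone, smooth muscle markers had 1 lower, Schwann cell markers 4 higher, heat shock genes 3 higher and 7 lower and glycolysis 3 higher, and the others had the counts given.

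The share of slow myosin heavy chain was taken as Myh7 as a percent of Myh7, Myh2 and Myh1. It was 1.12 ± 0.78% (SD, n = 7) in MSTN+/- libraries and 51.2 ± 34.9% (SD, n = 3) in wild type. Wild-type replicates 1, 2 and 3 were unlike, at 10.9%, 72.3% and 70.4%. The exact permutation p was at its smallest value, 0.00833 (two-sided). The 3 chains together reached only 7.44 to 20.2 FPKM in MSTN+/- libraries and 1.01, 0.47 and 0.27 FPKM in wild-type replicates 1, 2 and 3, and Myh7 itself was at 0.07 to 0.34 FPKM in all 10 libraries. The difference therefore rested on Myh2 and Myh1. Measured by troponin, Tnnt1 as a percent of Tnnt1 and Tnnt3, the share differed by -2.71 percentage points with an exact permutation p of 0.867. Tnnt1, at 0.19 to 3.81 FPKM, and Tnnt3, at 0 to 1.04 FPKM, were also low, so the troponin share is no firmer than the myosin share.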

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

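The outlier check was set before the data were examined. It asked, for 52 values within the 7 libraries labelled MSTN+/-, whether the highest or lowest library stood apart from its nearest neighbour by a larger part of the whole range than Dixon's critical value allows. Chance flags about 1 in 20 such groups, and 11 of the 52 stood apart. MSTN+/- replicate 7 was the library in 9 of the 11, and these values are not independent, since 4 of them are proteasome genes or their list.

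In replicate 7 the mean of the proteasome list was the lowest of the 7 libraries, with a gap of 0.748 of the range, as were Psmc3 (62.3 FPKM, gap 0.734), Psmd1 (44.0 FPKM, gap 0.682), Psmd11 (43.0 FPKM, gap 0.588) and Tpm3 (160 FPKM, gap 0.576). The same library was the highest in Col15a1 (71.9 FPKM, gap 0.733), Tef (31.5 FPKM, gap 0.663) and Pi16 (30.3 FPKM, gap 0.618). It was also the highest in Mstn (0.18 FPKM, gap 0.763), a level near 0. Its relative depth, 1.11, lay inside the range of the others. Apod was lowest in MSTN+/- replicate 4 (220 FPKM, gap 0.603). The share of slow myosin was highest in MSTN+/- replicate 1, at 2.82% with a gap of 0.726, in the library whose 3 heavy chains summed to the least, 7.44 FPKM.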

How the results depend on the processing

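The fit against wild-type replicate 1 alone was chosen after seeing the data, and the other alternatives before. Lower genes numbered 3137 with median-of-ratios scaling, 3851 with quantile normalization and 3368 with library weights, against 1800, and higher genes numbered 2874 with quantile normalization, against 4468. Leaving out 1 library gave 3445 to 5898 higher and 791 to 4449 lower genes. Lists called lower numbered 3 with median-of-ratios scaling, TPM and a pseudocount of 0.1, 2 with no low-value filter and with library weights, 5 against wild-type replicate 1 alone and 0 with an estimated correlation, against 1. Lists called higher numbered 7 with quantile normalization and 0 with an estimated correlation, against 4. Leaving out 1 library gave 3 to 7 lists higher and 1 to 3 lower. Quantile normalization turned the difference in MSTN level, near 0 throughout, to -0.031, and leaving out 1 library gave -0.00478 to 0.0422. The difference in slow myosin share was -70.2 to -39.5 percentage points with 1 library left out and -2.71 (exact permutation p = 0.867) from troponin. The extracellular matrix list reversed its camera direction against wild-type replicate 1 alone (median 0.10). The cause of these shifts was not tested. Among 43 named genes, 771 of 803 alternative fits kept direction and side of the threshold, 32 lost the call and 0 changed sign. The calls most often lost were those of Fabp3, in 10 of 19. A pseudocount of 0.1 gave log2 changes of 3.21 to 6.84 for Myoz2, Myh1, Mx2, Mx1, Myh2 and Pi16 and -5.14 for Mcpt8, over 1.5 times those with a pseudocount of 1. Fits in which Nlrp4f, Mcpt8, Myoz2 or Myh1 fell below the filter (Myh1 only at a mean of at least 5 FPKM) gave no value. The library-weight estimate stopped before reaching its tolerance. The planned count test was not run, since whole reads were not recovered from FPKM rounded to 2 decimals. Without total depth, no detection limit can be given for genes at 0. No paired analysis was possible because the labels give no replicate numbers, and those used here only name libraries.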

Other observations

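The tests of read origin, cell populations, mixture and marker correlation were chosen after the results were seen, as were the marker lists. The random splits and the depth test were set before their results were seen. The test of 4 factors was set before Klf4 and Myc were looked at, but after Pou5f1 and Sox2 had been seen to be high. Genes of MHC class I presentation, the display of peptides to T cells, were higher in the libraries labelled MSTN+/-. This held for 12 of 12 members, class I molecules and genes that serve them, at a limma adjusted p under 0.05. Their median log2 change was 2.90. H2-K1 was at 371 to 474 FPKM in the MSTN+/- libraries and at 11.97, 45.9 and 17.2 FPKM in wild-type replicates 1, 2 and 3. The light chain gene B2m was at 1518 to 2305 FPKM and at 362, 372 and 172 FPKM. The immunoproteasome genes Psmb8 and Psmb9 were at 33.4 to 50.3 and 16.9 to 27.4 FPKM and at most at 5.07 and 1.92 FPKM in wild type.

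Wild-type replicates 2 and 3, alike in most genes, were far apart in a few. Atp6v0c-ps2 was at 151 and 0.75 FPKM, and Hist1h2an was at 140 FPKM and listed at 0. The Y-linked Eif2s3y was at 35.9 FPKM in replicate 2 and 3.44 FPKM in replicate 3, and at 20.03 to 33.1 FPKM in the other 8 libraries. Other Y-linked genes were also lower in replicate 3 than in replicate 2. Kdm5d was at 3.23 and 0.81 FPKM in replicates 2 and 3, Uty at 5.43 and 2.32 FPKM and Ddx3y at 9.51 and 4.54 FPKM. Usp9y was near 0 in every library. Xist was not far apart between the 2 replicates, at 3.05 and 2.57 FPKM, and was at most at 0.33 FPKM elsewhere.

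Most muscle transcripts were near 0 in libraries labelled muscle, with Mylpf, at up to 155 FPKM, as an exception. Their median over 30 transcripts was at most 0.56 FPKM in any library. Cattle muscle reads counted on mouse genes would leave transcripts found only in rodents near 0. The brain cytoplasmic RNA Bc1 was at 343 to 1435 FPKM and Ly6a at 22.6 to 1510 FPKM in all 10 libraries, values that argue against such reads as the whole cause, although both had been seen before they were chosen. Reads of a mouse experiment can leave such transcripts present, as Bc1 and Ly6a were. The test set for such reads could not decide, and whether the table belongs to another study stays open. Of 5 rodent-only transcripts Bc1, Ly6a and Ly6c1 (3.05 to 562 FPKM) had been seen before. Of the other 2, Ly6c2 was at 0.27 FPKM at most. Rhox5 was at 0.76 FPKM in wild-type replicate 1, its lowest library, and at 205 FPKM in wild-type replicate 2. Their low values do not speak against mouse reads, since Ly6c2 shares sequence with Ly6c1 and Rhox5 varied widely between libraries. No biological explanation was tested.

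The 3 libraries labelled wild type differed from one another. They carry the same genotype label, so the design names no biological difference between them. Depth is argued against: among genes of at least 100 FPKM the highest correlation of replicate 1 with replicates 2 and 3 was 0.564, below the lowest between MSTN+/- libraries, 0.936. Pluripotency markers were lower in replicate 1 by a median log2 difference of -6.27 against replicate 2 and -6.16 against replicate 3, and fibroblast markers higher by 2.84 and 3.44 respectively. This suggests, as a hypothesis, different cell populations, fibroblast-like in replicate 1 and pluripotent-like in replicates 2 and 3, although the labels name neither. Of the 18 fibroblast markers several, such as Vim and Col1a1, are also made in muscle tissue.

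Pou5f1 and Sox2 were high beside low Nanog in the MSTN+/- libraries. A mixture of cells like wild-type replicate 1 with cells like replicates 2 and 3 is argued against, since the lowest Pou5f1 in the 7 libraries was 1.19 times the highest in wild type, while 24 other pluripotency markers implied a share of 0.81% to 17.9%. An excess supply of Pou5f1, Sox2, Klf4 and Myc together, as in reprogramming, was set out before Klf4 and Myc were looked at. Pou5f1 and Sox2 had already been seen to be high, so only Klf4 and Myc could give new support. It would put all 4 above every wild-type library in all 7, and 3 of the 4 were: Pou5f1, Klf4 (348 to 616 FPKM against at most 156) and Myc (251 to 379 FPKM against at most 43.2). Sox2 was above in 6 of 7, at 212 FPKM in the lowest against 224 FPKM, so an excess supply of all 4 factors may hold but stays open, since FPKM per gene cannot tell a supplied copy from the resident gene.

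Among the 7 MSTN+/- libraries, the mean of those 24 pluripotency markers and that of the fibroblast markers were inversely related, with Pearson's r of -0.766 (exact permutation p = 0.0429) and Spearman's rho of -0.75 (exact permutation p = 0.0663), both 0.0663 after Benjamini-Hochberg adjustment over these 2 measures. Without the 2 libraries farthest from the median, r was -0.782. The relation is a hypothesis that fails the correction.

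In 100 splits of the 10 libraries into 7 and 3, the real one included, 1 gave as many higher genes as the real 4468 (highest other 2418). As many lower genes as the real 1800 came from 3 splits (highest other 3052). Both shares are under 0.05, but the splits treat all libraries as alike, while wild-type replicates 2 and 3 form a close pair. For higher genes no other split drawn reached the real count, but only the real split keeps the 7 MSTN+/- libraries together. Those 7 are close to one another, so this rank does not by itself argue against chance. For lower genes the 2 other splits with larger counts kept that pair together, so chance is not excluded. Of the other splits, 6 put wild-type replicates 2 and 3 together with 1 MSTN+/- library. Among these 6, the splits with MSTN+/- replicates 4 and 2 called many genes, 2418 and 1664 higher and 3052 and 1894 lower. The remaining 4, and all splits that parted these replicates, called at most 3 genes each. For gene lists chance is not excluded: 25 of the 100 splits gave as many lists higher as the real 4 (highest other 6) and 96 as many lower as the real 1 (highest other 6).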
